A study of Mus musculus with 12 samples.

How the data were processed

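RNA was measured in 12 libraries of mouse rod photoreceptors, the light-sensing neurons that serve dim-light vision. The retinas had been electroporated, which drives plasmid DNA into cells by an electric pulse, and were dissociated at postnatal day 8. GFP-positive rods were then picked by hand with a micromanipulator, and each library was made from 50 to 100 cells with the SMARTer Stranded Total RNA-Seq Pico kit, which amplifies total RNA by PCR without molecular identifiers, and was sequenced from paired ends. Per the labels, 3 independent RNA samples were prepared for each of 4 treatments: a short hairpin RNA (shRNA) against mouse Csnk2a1, its control shRNA, the expression vector pcDNA4c carrying mouse Csnk2a1, and pcDNA4c as control. Whether the 3 samples came from separate animals is not stated, so p-values measure the spread between these samples.

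The submitters' processing notes name kallisto 0.45.0, edgeR 3.28 and the mouse build mm10, with no order or settings, and the annotation release is not given in the sources used here. The deposited gene table holds estimated counts (expected counts that need not be whole) for 52962 genes in 12 libraries, with no normalization between libraries, and 100% of its values above 0 were not whole. The deposited transcript table, whose title calls it raw counts, holds transcripts-per-million (TPM) values for 141196 transcripts, because each of its 12 columns sums to the fixed total of that unit. The third deposited table holds a scaled signal in counts-per-million (CPM) units of an effective library size. Each of its values equalled the gene value times 1 constant per library, with a largest relative departure of 7.77e-15, and its columns summed to between 923151 and 1100487. That table, as used here, covers 11 libraries, and pcDNA4c mCsnk2a1 1 was not analysed here on that scale. Of the deposited genes 98.0% were found in GENCODE mouse release M21 (GRCm38), and 99.5% of those had the same chromosome, start and end there, so positions are given on GRCm38 (mm10).

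The estimated counts were rounded to whole numbers and analysed with R 4.3.3 and edgeR 4.0.16. Genes with low counts were removed by filterByExpr with a minimum count of 10, which left 20267 genes, and libraries were scaled by the trimmed mean of M-values (TMM). All 12 libraries entered a single quasi-likelihood fit with 4 groups. The contrasts were knockdown (shRNA mCsnk2a1 minus shRNA Control), overexpression (pcDNA4c mCsnk2a1 minus pcDNA4c Control), the overexpression effect minus the knockdown effect, and, as a yardstick, shRNA Control minus pcDNA4c Control. Knockdown and overexpression name the construct and its intended effect. Genes with a Benjamini-Hochberg adjusted p under 0.05 passed. Fold changes are log2 values from edgeR, and levels are TMM-scaled CPM as mean ± SD. The standard error (SE) of a fold change is its size divided by the square root of the quasi-likelihood F statistic. It restates the test and was not estimated separately. For a gene without a count in a group, a lower bound of the fold was computed against a floor of 3 counts over that group. Bounds and intervals cover counting error only, since PCR copies are not independent molecules. Single measures were compared by two-sided exact permutation tests of 3 against 3 libraries, whose smallest possible p is 0.1.

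A total of 23 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, again with an estimated correlation, and with fry, whose directional p tests whether the genes of a list move, on balance, in 1 direction and does not compare the list with other genes. Adjusted p values of lists cover the 23 lists of a comparison. The lists were CK2 subunits, rod phototransduction, outer segment and cilium, NRL-dependent rod genes, photoreceptor transcription factors, cone genes, photoreceptor synapse, bipolar cells, Müller glia, amacrine and horizontal cells, retinal ganglion cells, progenitors and cell cycle, pigment epithelium, microglia, vascular and blood cells, p53 targets and apoptosis, integrated stress and unfolded protein response, immediate early genes, interferon response, Wnt/beta-catenin targets, mitochondrially encoded genes, cytosolic ribosomal proteins, and nuclear-encoded oxidative phosphorylation. List medians are medians of log2 CPM differences between groups. Where a member had no count in a group of a printed comparison of a pair of groups, a median of log2 ratios of summed levels with that group set to the floor is also given; it differs from the first median for the other members too. Some lists share members (Gnat1 and Mef2c among them), so their tests are not independent.

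The lists, contrasts, tests, alternative settings and the rule for naming genes were fixed before the data were examined. Under that rule, named genes passed the threshold, had 3 libraries of a group all above the 3 of the other, and were not predicted genes or pseudogenes. The 10 with the smallest p per direction were taken (5 for the difference between the effects). Where fewer than 5 passed, those with the smallest unadjusted p were added and are given as values. Csnk2a1, Csnk2a2, Csnk2b, Nrl, Crx, Nr2e3, Gnat1, Pde6b, Opn1sw, Arr3 and up to 4 members per list were fixed additions. Other genes were named after their values were seen, and this is said beside them. Single-gene results of a few genes that met these rules are not reported here, although the genes remain in the lists and counts.

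The tests were tried on simulated data of 20267 genes with the depth of these libraries, in which 50 genes each were changed 4-, 16-, 64- and 256-fold. The changed genes were drawn from those above the median mean level, so recovery of genes with lower counts was not tried. Each gene had the spread of the joint fit in all groups, so unequal spread between groups was not tried either. With the knockdown design edgeR recovered 1, 25, 32 and 40 of the 50 genes, and called 5 unchanged genes. With the overexpression design it recovered 4, 30, 40 and 44, and called 10 unchanged genes. The DESeq2 1.42.0 Wald test called 115 and 124 unchanged genes in these designs, and limma voom 38 and 32. The 12 pairs of libraries within groups were compared for duplication, and none had identical values or differed by as little as sampling noise. The replicate numbers of the titles did not pair libraries across groups: deviations from the group means correlated at between -0.0398 and 0.00873 across genes for the 6 pairs with the same number.

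Alternatives were DESeq2 size factors, library size only, no filter, a filter of 50 counts in 3 libraries, the DESeq2 Wald test, limma voom with sample quality weights, the replicate number as a block, limma on log2 of the deposited CPM plus 1, mitochondrially encoded and ribosomal RNA genes left out, only the 6 libraries of a comparison, an adjusted p under 0.1, and leaving out each library in turn. After the data were seen, thinning all libraries to the smallest total of 1609099 counts and leaving the 3 pcDNA4c Control libraries out of the knockdown fit were added. The genes Guca1a and Cabp4 have copies with identical values on patch sequences of the assembly, which were left out of the lists. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for checks and plots.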

Results

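The series addressed how protein kinase CK2 bears on gene expression driven by NRL, the transcription factor that specifies rod identity. CK2 is a ubiquitous serine/threonine kinase, and Csnk2a1 encodes its alpha catalytic subunit. The 12 libraries fell into 4 groups of 3, with Csnk2a1 targeted by an shRNA or supplied from an expression vector, each beside its own control group. Summed estimated counts were 1856775, 1608926 and 1683277 for shRNA Control, 2840426, 3567121 and 3061906 for shRNA mCsnk2a1, 2017623, 1986142 and 1692419 for pcDNA4c Control, and 2296056, 3551328 and 3287136 for pcDNA4c mCsnk2a1. The Csnk2a1 libraries were deeper than their controls in both arms (exact permutation p = 0.1 each, the smallest possible). After thinning to 1609099 counts, 20962 ± 974 genes had at least 1 count in shRNA Control, 18156 ± 1664 in shRNA mCsnk2a1, 23592 ± 1471 in pcDNA4c Control and 16651 ± 1562 in pcDNA4c mCsnk2a1 (SD, n = 3 per group; exact permutation p = 0.1 in both arms). Mitochondrial transcripts held 8.51% ± 0.224, 10.8% ± 0.610, 8.04% ± 0.671 and 11.3% ± 1.63 of the counts in the same order (SD, n = 3; exact permutation p = 0.1 in both arms). Most of this share was mitochondrial ribosomal RNA, at 6.99% to 7.41%, 8.74% to 10.2%, 6.34% to 7.37% and 7.34% to 9.95% by library. The mitochondrially encoded list, which holds no ribosomal RNA, had a median log2 difference of 0.12 with knockdown and 1.24 with overexpression.

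**Figure D1:**
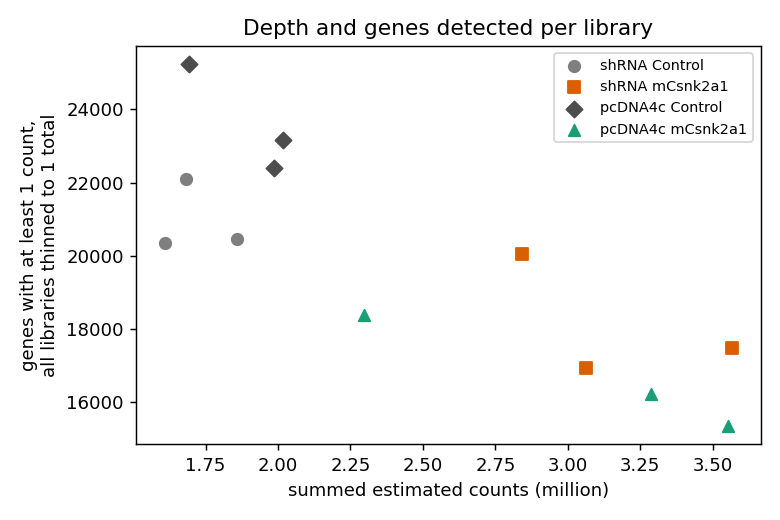
Each point is 1 of the 12 rod libraries, with its summed estimated counts on the x axis and the number of genes with at least 1 count after thinning to 1609099 counts on the y axis. The pcDNA4c Control libraries detected at least 22391 genes, more than any other library.

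Libraries of few cells varied widely. The biological coefficient of variation in edgeR was 1.17 for shRNA Control, 1.40 for shRNA mCsnk2a1, 0.890 for pcDNA4c Control, 1.54 for pcDNA4c mCsnk2a1 and 1.26 in the joint fit. Across 14284 genes the rank correlation between libraries of pcDNA4c Control was 0.644 to 0.662. It was 0.472 to 0.555 within the other 3 groups and 0.471 to 0.585 between groups. Genes are not independent replicates, so these coefficients describe similarity only.

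Csnk2a1 itself (ENSMUSG00000074698, chromosome 2, 152226839 to 152281852) was measured at 44.2 ± 31.3 CPM in shRNA Control, 23.4 ± 12.0 in shRNA mCsnk2a1, 46.6 ± 34.7 in pcDNA4c Control and 105 ± 49.5 in pcDNA4c mCsnk2a1 (SD, n = 3). The knockdown difference was -0.92 on the log2 scale (SE 0.88, edgeR adjusted p = 0.905; exact permutation p = 0.6). The overexpression difference was 1.18 (SE 0.88, edgeR adjusted p = 0.801; exact permutation p = 0.2). Neither exceeded the spread between libraries, and the single library shRNA Control 3 held 8.51 CPM, below the 3 knockdown libraries. The full-length coding transcript Csnk2a1-201, of 4206 nucleotides with 1173 coding, gave 2.78 ± 1.62 TPM in shRNA Control, 2.99 ± 2.92 in shRNA mCsnk2a1, 2.32 ± 0.499 in pcDNA4c Control and 5.01 ± 2.24 in pcDNA4c mCsnk2a1 (exact permutation p = 0.9 and 0.2 for the arms, n = 3). Counts with the expression vector can include transcripts of the plasmid. The other subunit genes did not pass in either arm. Csnk2a2, the alternative catalytic subunit, differed by 2.98 (SE 1.34, edgeR adjusted p = 0.598) with knockdown and by 0.15 (SE 1.24) with overexpression, and Csnk2b, the regulatory subunit, by 0.24 (SE 0.69) and 0.52 (SE 0.70). As a list the 3 subunits had medians of 0.27 with knockdown (camera adjusted p = 0.621) and 0.34 with overexpression (0.337), with 0 past the threshold adjusted over the list alone.

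**Figure D2:**
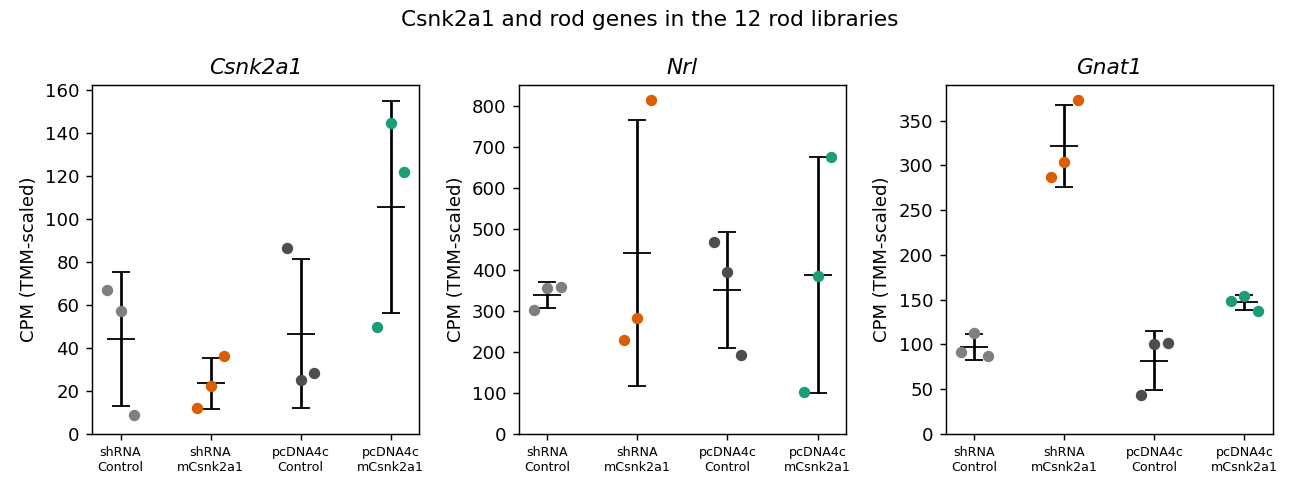
Level in TMM-scaled CPM on the y axis of Csnk2a1, Nrl and Gnat1 in the 4 groups on the x axis, with 1 point per library, the horizontal line at the mean and the error bar at ± 1 SD (n = 3). Csnk2a1 and Nrl overlap between each Csnk2a1 group and its control, while the 3 Gnat1 values of each Csnk2a1 group lie above the 3 of its control.

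With Csnk2a1 knockdown no single gene passed, and the list of rod phototransduction genes was higher in camera (adjusted p = 1.04e-07) but not with an estimated correlation (adjusted p = 0.195). Gnat1, the rod transducin alpha subunit (chromosome 9, 107674474 to 107679712), was 97.1 ± 14.1 CPM in shRNA Control and 321 ± 45.9 in shRNA mCsnk2a1 (SD, n = 3), a log2 difference of 1.73 (SE 0.49, edgeR adjusted p = 0.598). Sag, the rod arrestin, was 1639 ± 330 and 3368 ± 303 CPM, a difference of 1.04 (SE 0.29, adjusted p = 0.598). Over the 20267 genes tested with edgeR 0 passed. At an unadjusted p under 0.05 there were 1688 genes, DESeq2 called 183, limma voom 1 and limma on the deposited CPM 5, and 12.3% of genes had groups that did not overlap, where chance gives 10%. The mitochondrial share, most of it ribosomal RNA, was higher, and fewer genes were detected, in the same 3 libraries.

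Nrl itself (chromosome 14, 55518978 to 55524981) was 339 ± 31.4 CPM in shRNA Control and 442 ± 325 in shRNA mCsnk2a1 (log2 difference 0.39, SE 0.58, edgeR adjusted p = 0.990). Its sign rests on shRNA mCsnk2a1 3, at 816 CPM, and turned to -0.41 without that library. Crx, the homeobox factor that acts with NRL, differed by 0.76 (SE 0.31, adjusted p = 0.598). Nr2e3, the nuclear receptor that represses cone genes in rods, differed by 0.23 (SE 0.41), and Pde6b, a subunit of the rod phosphodiesterase, by 0.76 (SE 0.39). Of cone genes, Arr3, cone arrestin, differed by 1.12 (SE 2.36), and Opn1sw, the short-wavelength cone opsin, had no count in shRNA Control and 16.4 ± 11.1 CPM with knockdown, at least 30.6-fold higher (adjusted p = 0.598). Among the genes with the smallest p on the higher side were the 12S ribosomal RNA gene mt-Rnr1 (0.67, SE 0.12, adjusted p = 0.352), Rpl26 (2.89, SE 0.67), Luzp1 (5.88, SE 1.41) and Trub2 (4.37, SE 1.09). Among those lower were Dab2, an endocytic adaptor, with no count in shRNA mCsnk2a1 and 67.7 ± 38.1 CPM in the control, at least 195-fold lower (adjusted p = 0.0983), Atf7 (-3.74, SE 0.74, adjusted p = 0.484), Hmcn1 (-5.75, SE 1.23), Ptprv (-8.79, SE 1.92) and Coq4 (-6.54, SE 1.54). None of these passed in the main edgeR fit. Among the alternatives mt-Rnr1 passed in 4 of 23, and Dab2, Atf7 and Ptprv in 3 of 24 each. Rpl26, Luzp1 and Hmcn1 passed in 2 of 24 each, Coq4 in 2 of 23 and Trub2 in 1 of 24. The levels of Hmcn1, Ptprv and Coq4 in shRNA Control were 504 ± 457, 450 ± 538 and 115 ± 165 CPM, so their spread was about as large as their mean.

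As groups, 9 of the 23 lists passed camera with knockdown, all upward, and 0 passed with an estimated correlation. With fry 5 lists passed, 4 upward and microglia downward. Fry adjusted p values were 0.00497 for rod phototransduction, 2.23e-04 for NRL-dependent rod genes, 0.00241 for cone genes and 0.00354 for Müller glia. Fry does not compare a list with other genes. All 19 measured rod phototransduction genes were higher, with a median log2 difference of 1.06 (camera adjusted p = 1.04e-07; adjusted p = 0.195 with an estimated correlation). Adjusted over the list alone 6 passed, among them the exchanger Slc24a1 (2.90, SE 0.77), the transducin gamma subunit Gngt1 (1.18, SE 0.33) and Sag. Of 16 NRL-dependent rod genes 15 were higher, with a median of 1.24 (camera adjusted p = 1.00e-05; adjusted p = 0.0691 with an estimated correlation), and 5 passed adjusted over the list alone. Of 26 outer segment and cilium genes 22 were higher (median 0.66, adjusted p = 0.00574; 0.335 with an estimated correlation), such as Prph2 (1.12, SE 0.36) and Rp1 (0.74, SE 0.28). Of 18 photoreceptor transcription factors 15 were higher (median 0.46, adjusted p = 0.00622; 0.335 with an estimated correlation), and of 18 photoreceptor synapse genes 15 (median 0.56, adjusted p = 0.00622; 0.335 with an estimated correlation), such as the vesicular glutamate transporter Slc17a7 (1.26, SE 0.48). In these 3 lists 0 genes passed adjusted over the list alone. The outer segment call ended without shRNA mCsnk2a1 2 or shRNA Control 3, that of transcription factors without shRNA Control 3, and that of the synapse without shRNA mCsnk2a1 2 or under the filter of 50 counts in 3 libraries.

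Lists outside the rod program passed camera as well. Of 15 cone genes 11 were higher (median 1.43, and 1.37 with groups at 0 set to the floor; camera adjusted p = 0.00428; adjusted p = 0.0691 with an estimated correlation), with 0 past adjusted over the list alone. Of 13 Müller glia genes 11 were higher (median 1.16, adjusted p = 0.00464; adjusted p = 0.0691 with an estimated correlation). Adjusted over the list alone 2 of them passed, the lipid carrier Apoe (1.46, SE 0.44) and the glial glutamate transporter Slc1a3 (1.94, SE 0.59). Of 74 nuclear-encoded oxidative phosphorylation genes 55 were higher (median 0.44, adjusted p = 0.00206; adjusted p = 0.301 with an estimated correlation), and of 78 cytosolic ribosomal protein genes 55 (median 0.30, and 0.33 with groups at 0 set to the floor; adjusted p = 0.00391; adjusted p = 0.335 with an estimated correlation), with 1, Rpl26, past adjusted over the list alone. The cone list lost its call under the filter of 50 counts in 3 libraries, and the ribosomal list without shRNA mCsnk2a1 1.

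The other lists did not pass camera with knockdown. Of 11 microglia genes 10 were lower (median -0.74, and -2.07 with groups at 0 set to the floor; adjusted p = 0.136), with 2 past adjusted over the list alone, Cd68 at least 36.8-fold and Ctss at least 16.8-fold lower, while fry gave an adjusted p of 0.00147. The Ctss fold rests on 31 counts in the single library shRNA Control 3 and is 0 without it. Medians and camera adjusted p were 0.41 and 0.211 for bipolar cells, -0.78 and 0.520 for amacrine and horizontal cells, 0.56 and 0.515 for progenitors and cell cycle, -0.41 and 0.967 for pigment epithelium, and -0.44 and 0.621 for vascular and blood cells. They were 0.23 and 0.621 for p53 targets and apoptosis, 0.44 and 0.424 for the integrated stress and unfolded protein response, 0.63 and 0.234 for immediate early genes, 0.41 and 0.535 for the interferon response, and -0.24 and 0.799 for Wnt/beta-catenin targets. With groups at 0 set to the floor the medians were 0.58 for progenitors and cell cycle, 0.65 for the interferon response and -0.64 for Wnt/beta-catenin targets, and that of pigment epithelium turned sign to 0.68. The ratios of summed levels also turned the sign for amacrine and horizontal cells (0.25) and the stress response (-0.03), so these medians set no direction. Retinal ganglion cell genes had a median of -0.55, which turned to 0.36 with groups at 0 set to the floor, a mean of 0.60 and an upward camera direction (adjusted p = 0.246), with 1 of 8, Slc17a6, at least 53.2-fold higher, past adjusted over the list alone. Mitochondrially encoded genes had a median of 0.12, a mean of -0.22 and an upward direction (adjusted p = 0.673). In the other lists of this paragraph 0 genes passed adjusted over the list alone. The median log2 difference over all genes was -0.12, and scaling by library size alone shifted it by -0.16.

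With Csnk2a1 overexpression, several genes typical of macrophages and microglia were lower than in pcDNA4c Control. The 7 genes that passed lower were also lower in shRNA Control than in pcDNA4c Control. All 12 mitochondrially encoded genes were higher and 5 passed. That list passed fry (fry adjusted p = 2.41e-04) but not camera with an estimated correlation (adjusted p = 0.0726). Spp1, the secreted phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050), was at 2015 ± 268 CPM in pcDNA4c Control and at 0 in pcDNA4c mCsnk2a1 (SD, n = 3), at least 5712-fold lower (edgeR adjusted p = 0.00198). Apoe (chromosome 7, 19696109 to 19699188) fell by 3.43 on the log2 scale (SE 0.47, adjusted p = 0.00250), from 1084 ± 153 to 101 ± 22.7 CPM. Mitochondrial mt-Nd2, a subunit of respiratory complex I, rose by 2.01 (SE 0.29, adjusted p = 0.00376), from 526 ± 59.1 to 2115 ± 629 CPM. The homeobox gene Prox1 (chromosome 1, 190118035 to 190170714) rose by 3.94 (SE 0.62, adjusted p = 0.00783), from 18.9 ± 4.62 to 291 ± 138 CPM, where shRNA Control stood at 131 ± 79.5. The Prox1 call ended without pcDNA4c mCsnk2a1 3 or any 1 of the pcDNA4c Control libraries, with limma voom and with only the 6 libraries of the comparison. In all, 20 of 20267 genes passed, 13 higher and 7 lower, and each had groups that did not overlap, as had 15.5% of all genes where chance gives 10%.

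The lower genes named by the rule were Spp1, the lysosomal protease Ctsl (-4.74, SE 0.64, adjusted p = 0.00250), Apoe, the lysosomal saposin precursor Psap (-3.08, SE 0.44, adjusted p = 0.00350), the macrophage perforin Mpeg1 (at least 501-fold, adjusted p = 0.00418) and the lysozyme Lyz2 (at least 960-fold, adjusted p = 0.00437). The seventh, the noncoding Gm26917, falls outside the rule and was named after its values were seen (-2.44, SE 0.36). In shRNA Control, Spp1 stood at 1.21 ± 2.10 CPM, Ctsl at 97.8 ± 7.11, Apoe at 102 ± 42.3, Psap at 71.2 ± 20.9, Mpeg1 at 0 and Lyz2 at 4.32 ± 6.60. Higher were the signal recognition particle RNA genes Rn7s1 and Rn7s2, whose values are identical (1.19, SE 0.13, adjusted p = 2.14e-04), mt-Rnr1 (0.88, SE 0.12, adjusted p = 0.00350), mt-Nd2, mt-Cytb (1.46, SE 0.23), mt-Nd5 (adjusted p = 0.0128), mt-Nd4 (1.55, SE 0.28), Rpl26 (4.17, SE 0.71) and Prox1, among others. Beyond the rule mt-Co1, the mitochondrial pseudogene Gm28437 and the glycolytic enzyme Eno1 also passed, at adjusted p of 0.0329, 0.0375 and 0.0382. With only the 6 libraries of the comparison 6 genes passed, all lower and 5 of them among the 20, and none of the named higher genes did (Rn7s1 adjusted p = 0.226). Leaving out pcDNA4c mCsnk2a1 2 or 3, or pcDNA4c Control 1, 2 or 3, gave 13, 11, 12, 11 and 11 genes, while Spp1, Apoe, Psap and Lyz2 passed under every alternative. Without pcDNA4c mCsnk2a1 2 or 3 or pcDNA4c Control 1, mt-Cytb, mt-Nd5, mt-Nd4, mt-Co1, Rpl26, Gm28437 and Eno1 each lost their calls, and Mpeg1 did without pcDNA4c Control 2 or 3.

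**Figure D3:**
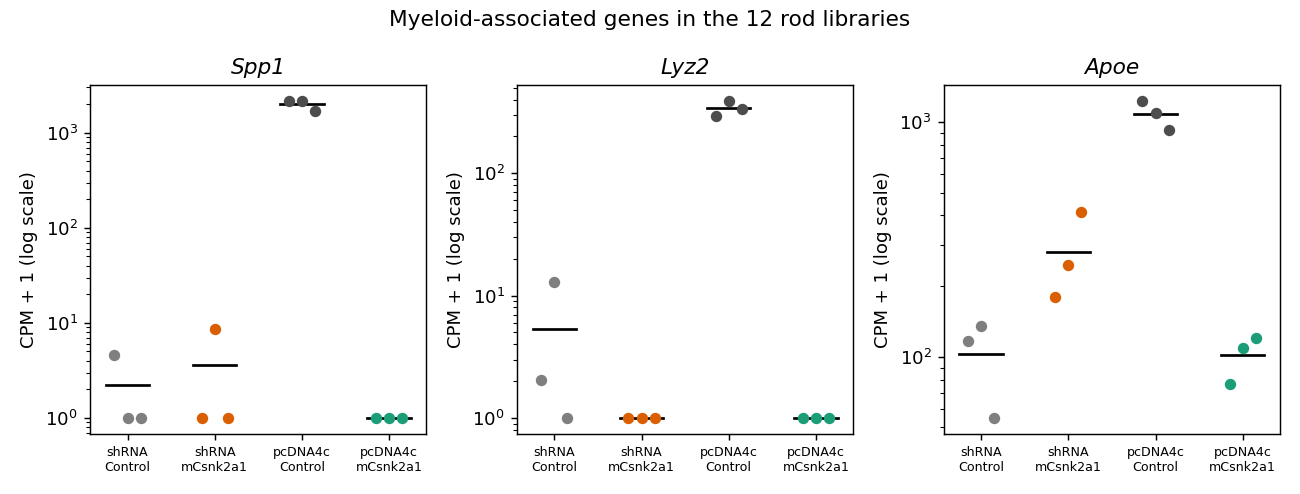
CPM plus 1 on a log y axis for Spp1, Lyz2 and Apoe in the 4 groups on the x axis, with 1 point per library and a line at the mean (n = 3). The 3 pcDNA4c Control libraries stand above the other 9 for Spp1, Lyz2 and Apoe, with Apoe at 926 CPM or more against at most 412.

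Single genes of the rod program did not pass with overexpression in the main edgeR fit. Nrl differed by 0.14 (SE 0.58; -0.53 to 0.66 over the alternatives), Crx by -0.02 (SE 0.30), Nr2e3 by -0.04 (SE 0.41), Gnat1 by 0.84 (SE 0.48), Pde6b by 0.80 (SE 0.39) and Arr3 by -0.25 (SE 2.33). Opn1sw had no count in pcDNA4c mCsnk2a1 and 22.6 ± 19.6 CPM in the control, at least 65.7-fold lower (adjusted p = 0.519). None of these passed in the main edgeR fit, and Opn1sw did in 1 of 21 alternatives. Of 19 rod phototransduction genes 14 were higher (median 0.31, and 0.53 with groups at 0 set to the floor; camera adjusted p = 0.00348; adjusted p = 0.477 with an estimated correlation), and 2 passed adjusted over the list alone, among them the transducin beta subunit Gnb1 (1.20, SE 0.36). That list lost its call without pcDNA4c mCsnk2a1 2 or 3. NRL-dependent rod genes did not pass camera in the main setting (10 of 16 higher, median 0.31, mean -0.12, upward, adjusted p = 0.0797), and passed in 5 of 25 alternatives. Adjusted over the list alone 2 passed higher, among them Gnb1, and Mef2c, a transcription factor also expressed in microglia, lower (-6.67, SE 1.52), at 169 ± 106 CPM in pcDNA4c Control and 5.52 ± 2.28 in shRNA Control.

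Of the 23 lists 7 passed camera with overexpression, 5 upward and 2 downward, and 2 of them, microglia and bipolar cells, also passed with an estimated correlation. Both also differed between the control groups, with medians of -3.93 and 1.59 in shRNA Control minus pcDNA4c Control. A trait of the pcDNA4c Control libraries is therefore not told apart from an effect of the construct by these calls. With fry 6 lists passed, 2 upward (bipolar cells, mitochondrially encoded genes) and 4 downward (microglia, cone genes, progenitors and cell cycle, immediate early genes). Cone genes had a fry adjusted p of 3.07e-04, and fry does not compare a list with other genes. Rod phototransduction was not among the 6 (fry adjusted p = 0.333). All 11 measured microglia genes were lower (median -3.89, and -3.12 with groups at 0 set to the floor; camera adjusted p = 1.47e-11; adjusted p = 0.00152 with an estimated correlation). Over all genes 0 of them passed in the main edgeR fit, and 4 passed adjusted over the list alone: the protease Ctss at least 535-fold, the complement genes C1qa at least 153-fold and C1qb at least 101-fold, and the adaptor Tyrobp at least 70.0-fold lower. Over all genes Ctss passed in 8 of 23 alternatives, C1qa in 2 of 23, C1qb in 1 of 23 and Tyrobp in 0 of 22. Of 14 bipolar cell genes 13 were higher (median 1.98, and 1.87 with groups at 0 set to the floor; adjusted p = 7.51e-10; adjusted p = 0.00338 with an estimated correlation). Adjusted over the list alone 3 passed, among them Isl1 (2.64, SE 0.72) and Lhx4 (3.95, SE 1.20). All 12 measured mitochondrially encoded genes were higher (median 1.24, adjusted p = 1.34e-07; adjusted p = 0.0726 with an estimated correlation), 5 over all genes and 7 adjusted over the list alone. Of 15 cone genes 12 were lower (median -1.65, and -1.19 with groups at 0 set to the floor; adjusted p = 0.0275; adjusted p = 0.130 with an estimated correlation), with 0 past adjusted over the list alone. Cytosolic ribosomal protein genes (52 of 78 higher, median 0.28, adjusted p = 9.44e-05; adjusted p = 0.314 with an estimated correlation) had 1, Rpl26, past over all genes, and nuclear-encoded oxidative phosphorylation genes (41 of 74 higher, median 0.16, adjusted p = 0.00312; adjusted p = 0.314 with an estimated correlation) had 0. Both camera calls are relative to the other genes, and the median over all genes was -0.53. With fry neither list passed (fry adjusted p = 0.357 and 0.665). The cone call ended under several alternatives, among them only the 6 libraries of the comparison and leaving out pcDNA4c mCsnk2a1 1 or 3 or pcDNA4c Control 1, and that of oxidative phosphorylation without pcDNA4c mCsnk2a1 3.

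The remaining lists did not pass camera with overexpression. With fry, progenitors and cell cycle (fry adjusted p = 0.0253) and immediate early genes (0.0425) passed, both lower. The median log2 difference over all genes was -0.53, and camera tests each list against the other genes, so a list with a median near 0 can have an upward direction. This held for outer segment and cilium (median -0.25, mean -0.11, adjusted p = 0.305) and photoreceptor transcription factors (median -0.15, mean -0.50, adjusted p = 0.732), the latter with Mef2c past adjusted over the list alone. Müller glia genes (median 0.12, mean -0.29, upward, 0.591) included 1 that passed, Apoe, and amacrine and horizontal cell genes (median -0.21, mean 0.14, upward, 0.277) included Prox1. Medians and camera adjusted p were 0.12 and 0.104 for photoreceptor synapse, -0.80 and 0.934 for retinal ganglion cells, -0.70 and 0.421 for progenitors and cell cycle, 0.01 and 0.421 for pigment epithelium, and -1.14 and 0.732 for vascular and blood cells. They were -0.38 and 0.732 for p53 targets and apoptosis, -0.97 and 0.628 for the integrated stress and unfolded protein response, -0.81 and 0.307 for immediate early genes, -1.32 and 0.421 for the interferon response, and -0.14 and 0.934 for Wnt/beta-catenin targets. With groups at 0 set to the floor the medians of progenitors and cell cycle and of p53 targets and apoptosis turned sign, to 0.37 and 0.25, as did those of photoreceptor transcription factors (0.09) and of amacrine and horizontal cells (0.59) by summed levels. Those of vascular and blood cells, the stress response, immediate early genes and the interferon response were -1.44, -0.37, -0.35 and -0.82. Adjusted over the list alone 1 immediate early gene passed, Atf3, at least 115-fold lower, and 0 did in the outer segment list or the other lists given here by median.

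The control groups were compared as a yardstick, since they differ in vector and not in Csnk2a1. Between shRNA Control and pcDNA4c Control 14 genes passed in edgeR, 3 higher and 11 lower in shRNA Control, with 854 at an unadjusted p under 0.05. These genes were named after their values were seen. Lower were Spp1, Apoe, Psap, Mpeg1, Ctsl, the matrix protein Fn1 (-3.47, SE 0.63, adjusted p = 0.0437), the lipid exporter Abca1 (-3.46, SE 0.64, adjusted p = 0.0437), Gm26917, and the small RNA genes Gm23935, Gm24270 and Gm24245, whose values are identical and were 486 ± 71.7 CPM in shRNA Control and 6410 ± 90.5 in pcDNA4c Control (SD, n = 3; adjusted p = 4.04e-06). Higher were Rn7s1, Rn7s2 and mt-Rnr1. This comparison and overexpression share the 3 pcDNA4c Control libraries, so their genes are not independent. The microglia list was lower in shRNA Control (11 of 11, median -3.93, and -4.54 with groups at 0 set to the floor; camera adjusted p = 4.68e-16; adjusted p = 4.57e-04 with an estimated correlation), and the bipolar list was higher (11 of 14, median 1.59, and 1.53 with groups at 0 set to the floor; adjusted p = 1.24e-06; adjusted p = 0.0129 with an estimated correlation). The ribosomal protein list was higher (65 of 78, median 0.59, and 0.60 with groups at 0 set to the floor; adjusted p = 9.12e-06; adjusted p = 0.265 with an estimated correlation). The other 20 lists did not pass camera. With fry the cone list also passed, lower in shRNA Control (fry adjusted p = 0.00592, camera adjusted p = 0.106). Of its 15 genes 13 were lower, with a median of -0.96, and -0.83 with groups at 0 set to the floor. Rod phototransduction had a median of 0.03, a mean of -0.09 and an upward direction (adjusted p = 0.948), and CK2 subunits (median -0.28) and immediate early genes (median -0.37) also had upward directions.

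The overexpression effect minus the knockdown effect asks whether the expression vector and the shRNA acted differently, each against its own control, while a change of Csnk2a1 itself passed in neither arm. In edgeR 4 genes passed, all lower: Apoe (-4.88, SE 0.64, adjusted p = 0.00624), Spp1 (adjusted p = 0.00970), Psap (-3.60, SE 0.60, adjusted p = 0.0446) and Gm26917 (-2.95, SE 0.49, adjusted p = 0.0446), the last outside the naming rule and named after its values were seen. Spp1 was at 1.21 ± 2.10 CPM in shRNA Control and 2.56 ± 4.44 in shRNA mCsnk2a1, and Apoe at 102 ± 42.3 and 279 ± 121. At an unadjusted p under 0.05 there were 1691 genes. Among genes that did not pass, the rule added Ctsl (-4.08, SE 0.81, adjusted p = 0.172) and the nuclear RNA Malat1 (-1.83, SE 0.37, adjusted p = 0.209) on the lower side. On the higher side were Gpi1, a glycolytic enzyme (3.19, SE 0.69, adjusted p = 0.264), and Dab2, Vipr1, Dynlt1a and Afap1l2, which had no count in shRNA mCsnk2a1. The difference was 2.09 for Csnk2a1 (SE 1.24, adjusted p = 0.672), -0.24 for Nrl (SE 0.82), -0.79 for Crx (SE 0.43), -0.27 for Nr2e3 (SE 0.58), -0.88 for Gnat1 (SE 0.68) and 0.04 for Pde6b (SE 0.55). Psap lost its call in 14 of the alternatives, Gm26917 in 14, and Apoe in none. Spp1 lost it with limma voom, under the filter of 50 counts in 3 libraries, and without shRNA mCsnk2a1 2 or pcDNA4c mCsnk2a1 3.

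By list, 4 of 23 differed between the effects in camera, and 9 with fry (2 upward and 7 downward). Cone genes were lower with overexpression than with knockdown (12 of 15, median -3.16, and -2.95 over the 13 members with counts in every group; camera adjusted p = 4.14e-04; adjusted p = 0.0259 with an estimated correlation). Adjusted over the list alone 3 passed, among them Opn1sw and the cone thyroid hormone receptor Thrb (-3.03, SE 1.05), and 0 over all genes. Thrb stood at 46.8 ± 39.3 CPM in shRNA Control, 192 ± 115 in shRNA mCsnk2a1, 106 ± 17.2 in pcDNA4c Control and 53.3 ± 36.1 in pcDNA4c mCsnk2a1 (SD, n = 3). Microglia genes were lower (10 of 11, median -4.35, adjusted p = 1.06e-04; adjusted p = 0.0259 with an estimated correlation). Bipolar cell genes were higher (11 of 14, median 1.34, adjusted p = 0.00162; adjusted p = 0.0737 with an estimated correlation). Mitochondrially encoded genes were higher (12 of 12, median 1.27, adjusted p = 8.80e-04; adjusted p = 0.281 with an estimated correlation), with 6 past adjusted over the list alone. Of these mt-Nd5 stood at 1438 ± 204, 1509 ± 381, 1319 ± 201 and 3984 ± 971 CPM in shRNA Control, shRNA mCsnk2a1, pcDNA4c Control and pcDNA4c mCsnk2a1. Rod phototransduction (median -0.79, adjusted p = 0.118) and NRL-dependent rod genes (median -0.67, adjusted p = 0.117) did not pass camera. With fry the NRL-dependent rod genes passed, lower (fry adjusted p = 0.00284), and rod phototransduction did not (0.0838). Among the others, median, mean and direction differed in sign for CK2 subunits (0.07, -0.24, upward), pigment epithelium (-0.35, 0.47, upward), Wnt/beta-catenin targets (-0.52, -0.24, upward) and ribosomal proteins (-0.09, -0.29, upward). The cone call ended under the filter of 50 counts in 3 libraries (adjusted p = 0.0863) and the microglia call with DESeq2 statistics (0.170).

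**Figure D4:**
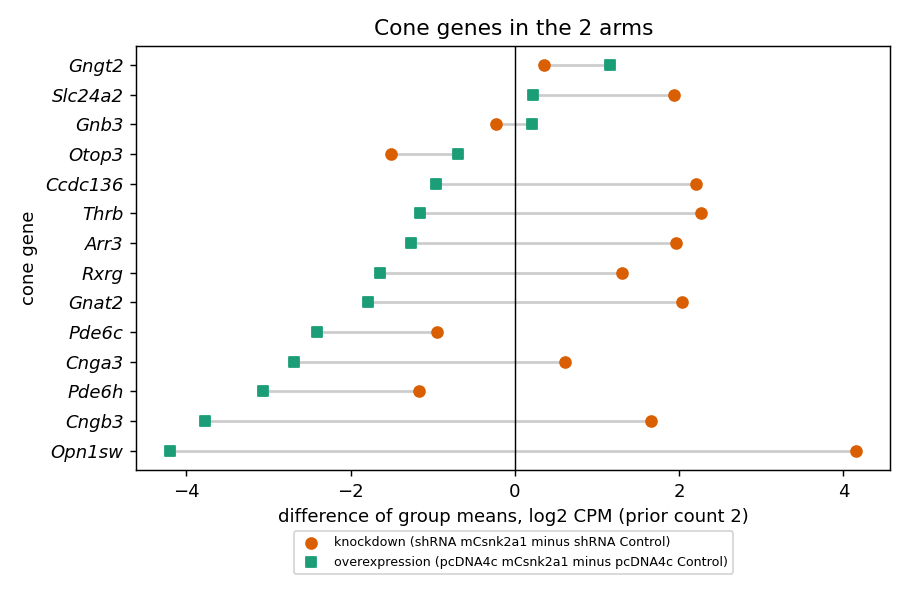
Cone genes (14 of the 15 measured) on the y axis, each with its difference of group means in log2 CPM on the x axis, circles for knockdown and squares for overexpression, joined by a line. In 11 of the 14 genes the overexpression value lies left of the knockdown value.

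Across the 20267 genes the knockdown and overexpression fold changes correlated with Pearson r = 0.0585, a Spearman coefficient of 0.0745 and a covariance of 0.120. The arms share no library, so relabelling libraries within each arm gives the chance level: 6 of 100 joint relabellings were as large in size (permutation p = 0.06 for each statistic), with a median absolute r of 0.0123 and a largest of 0.0938. Genes are not independent replicates, and this is why the relabellings and not the number of genes set the p.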

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

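The tests of myeloid genes between the control groups and of cone genes against the number of genes detected were chosen only after the results were seen. Every result here was singled out because the overexpression effect differed from the knockdown effect by a test of that difference. Apoe (edgeR adjusted p = 0.00624), Spp1 (0.00970), Psap (0.0446) and Gm26917 (0.0446) did so as single genes, and the microglia (camera adjusted p = 1.06e-04), cone (4.14e-04), mitochondrially encoded (8.80e-04) and bipolar cell lists (0.00162) as groups. For the number of single genes, 4, chance is not excluded. Of 60 splits of the libraries, drawn from 200 possible, 3 gave at least as many, the actual grouping among them. The highest of the others gave 6. These splits count calls and do not test any given gene. The bipolar list lost its call with an estimated correlation (adjusted p = 0.0737), and so did the mitochondrially encoded list (0.281), where the pcDNA4c mCsnk2a1 libraries alone stood high. The bipolar list was also higher in shRNA Control than in pcDNA4c Control, by a median of 1.59.

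Myeloid genes were lower with overexpression, and Csnk2a1 lowering a level that control rods share is argued against: genes that passed lower in fits without 1 pcDNA4c Control library, filtered anew, lay below that library in shRNA Control for 7 of 8, 8 of 8 and 10 of 10 genes (libraries 1, 2 and 3), with median log2 differences of -3.59, -4.85 and -4.58 against -0.21, -0.13 and -0.25 over all genes. RNA of macrophages or microglia in the pcDNA4c Control libraries is a candidate source, since the microglia list, fixed before the data were examined, had a median of -3.93 in the same control comparison. Of its 11 measured genes 7 had 3 pcDNA4c Control libraries above all other 9 libraries, 9 had counts in at least 1 of those 9, and Mef2c of the rod lists is also expressed in microglia. Among genes picked after their values were seen, Gpnmb stood at 858 CPM and Ctsd at 528 in pcDNA4c Control, but Abca1 at 475 against 462 in pcDNA4c mCsnk2a1, and Cst3 at 264 against 272 in shRNA mCsnk2a1, were not particular to it. Picking GFP-positive rods should have left such cells out, and a response to the empty vector alone was not tested. The pcDNA4c Control libraries also differed in RNA other than that of myeloid genes. Nuclear ribosomal RNA held 0.803% to 0.845% of their counts, against at most 0.607% in any other library. Signal recognition particle and 7SK RNA held 3.58% to 4.46%, against at least 5.62%. What set this group apart in these RNAs was not tested.

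Cone genes were lower with overexpression than with knockdown, with a median difference of -3.16 over 15 genes. A lower number of genes detected in the Csnk2a1 libraries is argued against, since that number was lower in both arms while the list medians were 1.43 and -1.65, and the difference was past the threshold with an estimated correlation (adjusted p = 0.0259). For camera with the preset correlation a single deciding library is argued against as well. There the highest adjusted p among the fits that leave out 1 library was 0.00231. Those fits were not tested with an estimated correlation, so the call with that setting was not checked for a deciding library. A high level in the pcDNA4c Control libraries alone may account for the overexpression side, since pcDNA4c mCsnk2a1 lay near shRNA Control, with a median log2 difference of -0.34. Whether Csnk2a1 acts on cone genes was not decided, since its own change passed in neither arm (edgeR adjusted p = 0.905 and 0.801) and counts were low, with Opn1sw at 0, 149, 136 and 0 summed counts in shRNA Control, shRNA mCsnk2a1, pcDNA4c Control and pcDNA4c mCsnk2a1 and the call lost under the filter of 50 counts in 3 libraries (adjusted p = 0.0863).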

How the results depend on the processing

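Thinning the libraries and leaving pcDNA4c Control out of the knockdown fit were chosen only after the results were seen; the other alternatives were planned. The counts of genes past the threshold, 0 with knockdown, 20 with overexpression, 4 for the difference and 14 between controls, moved most with other tests and filters. The voom setting adds sample quality weights, and limma on the deposited CPM works without pcDNA4c mCsnk2a1 1, so neither is a change of test alone. In that order they were 93, 111, 137 and 71 with no filter, 183, 253, 208 and 69 with DESeq2 (19, 4 and 12 of the edgeR genes shared in the last 3), 1, 34, 1 and 25 with limma voom, and 5, 48, 16 and 26 with limma on the deposited CPM. On simulated data with the same spread per gene in all groups, DESeq2 called 115 and 124 unchanged genes. Knockdown gave 1 at an adjusted p under 0.1. Overexpression gave 12 without mitochondrially encoded and ribosomal RNA genes and 6 with only its 6 libraries. Most of the fall to 12 was fixed in advance. That setting removes mt-Rnr1, mt-Nd2, mt-Cytb, mt-Nd5, mt-Nd4 and mt-Co1, which were among the 20. The difference gave 2 with DESeq2 size factors, with 50 counts in 3 libraries and with thinned libraries. Lists past the threshold, 9, 7, 4 and 3, were 0, 2 and 2 in the first 3 comparisons with an estimated correlation, 5 and 9 with fry for knockdown and the difference, and 7 and 5 with voom for the difference and the controls. The fry lists were 4 upward and 1 downward with knockdown, 2 and 4 with overexpression, and 2 and 7 for the difference. Where no cause is named, the cause was not tested.

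With the replicate number as a block the counts were 1, 26, 9 and 18, Csnk2a1 was -0.75 and 1.28, and r between the arms was 0.0585; the numbers did not pair the libraries. Leaving out 1 library gave 0 to 1 genes with knockdown (1 without pcDNA4c mCsnk2a1 1), 11 to 29 with overexpression (13 without pcDNA4c mCsnk2a1 2, 12 without pcDNA4c Control 1, and 11 without pcDNA4c mCsnk2a1 3 or pcDNA4c Control 2 or 3), 1 to 12 for the difference (1 without pcDNA4c mCsnk2a1 3, 12 without pcDNA4c mCsnk2a1 1, and 2 without shRNA mCsnk2a1 1, shRNA Control 1, 2 or 3, pcDNA4c mCsnk2a1 2, or pcDNA4c Control 1 or 2), and 9 to 16 between controls (9 without pcDNA4c Control 3). It gave 7 to 9, 4 to 9, 4 to 5 and 3 to 4 lists (4 with overexpression without pcDNA4c mCsnk2a1 3), Csnk2a1 at -1.40 to -0.49 and 0.88 to 1.98, and r at 0.0266 to 0.0875 (0.0411 without shRNA Control 3, 0.0875, 0.0416 and 0.0266 without pcDNA4c mCsnk2a1 1, 2 and 3, and 0.0379 without pcDNA4c Control 3). No gene or list that passed in either setting changed sign. Splits of 6 libraries number 10, too few for a share under 0.05: 10 of 10 gave at least the 0 genes of the knockdown (highest other 1), and the 20 of overexpression and the 14 between controls were each reached by 1 of 10 (highest other 0). Gene counts summed from the transcript table were not run, since it holds TPM. Counted as pairs of a result and a setting, for single genes and lists, 7265 and 2077 pairs kept direction and side of the threshold, 153 and 45 dropped out, 105 and 39 came in, and 103 and 112 changed sign without passing in either setting. Depth limits genes such as Opn1sw, whose groups at 0 summed counts allow only bounds.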

Other observations

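The test of a purer collection of rods was chosen only after the result was seen. Beyond the comparisons, transcripts better known from other retinal cells were measured in all 4 groups, and whether they came from the picked rods was not tested. In shRNA Control, shRNA mCsnk2a1, pcDNA4c Control and pcDNA4c mCsnk2a1, Prox1 stood at 131 ± 79.5, 291 ± 115, 18.9 ± 4.62 and 291 ± 138 CPM, and Slc1a3 at 80.7 ± 51.9, 310 ± 84.8, 47.1 ± 11.8 and 56.0 ± 10.3 (SD, n = 3). Abundant noncoding RNAs were measured as well. The signal recognition particle RNA gene Rn7s1 stood at 24392 ± 345 CPM in shRNA Control, 33592 ± 2694 in shRNA mCsnk2a1, 10800 ± 1509 in pcDNA4c Control and 24608 ± 3909 in pcDNA4c mCsnk2a1, and Malat1 at 6141 ± 1056, 10544 ± 3271, 11898 ± 3388 and 5742 ± 1842.

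Rod phototransduction genes were higher with the Csnk2a1 construct in both arms, by a mean log2 difference of 1.27 with knockdown and 0.35 with overexpression, but neither list call held with an estimated correlation (adjusted p = 0.195 and 0.477). Library depth is argued against as the whole account in the knockdown, since thinning to 1609099 counts left 1.18 (SD 0.0127 over 10 thinnings). Rods freer of every other cell type in the overexpression are argued against by the bipolar list, higher by a median of 1.98, though it was also 1.59 higher in shRNA Control than in the same pcDNA4c Control libraries, and rods freer of myeloid cells alone are not, with the microglia list at -3.89. A lower number of genes detected may account for part of the knockdown difference: over the 12 libraries, as deviations from the group means, it correlated with the list mean at Pearson r = -0.79 (permutation p = 0.00694, 1296 permutations) and a Spearman coefficient of -0.741 (permutation p = 0.0285), and at -0.627 without the 2 farthest libraries. That slope corresponds to 0.48 of the 1.27 in the knockdown and predicts 1.18 with overexpression against 0.35 measured, and whether Csnk2a1 acts on rod genes was not decided, since the knockdown of Csnk2a1 itself did not pass (edgeR adjusted p = 0.905).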
